A study of Mus musculus with 8 samples.

How the data were processed

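Gene expression was measured by bulk RNA sequencing in 8 libraries of CD8 T cells from the spleens of wild-type C57BL/6 mice, in 6 sorted groups. Per the labels, CD8 T cells were enriched on magnetic beads and then sorted as naive cells (CD44- CD49d-), true memory cells (CD44hi CD49d+) and virtual memory (VM) cells (CD44hi CD49d-), and the VM cells were divided by Ly6C and Sca-1. Virtual memory cells are memory-like CD8 T cells that arise without exposure to a foreign antigen. The titles were used to assign groups, because another label field calls the naive and true memory libraries virtual memory as well. Ly6C+ Sca-1- VM and Ly6C+ Sca-1+ VM had 2 libraries each, and the other 4 groups had 1 library each. The labels number the 2 libraries of a group, but the columns of the table carry a suffix instead, so the libraries are called A (no suffix) and B (suffix) here. What the suffix marks is not stated.

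Per the labels, libraries were stranded mRNA libraries (TruSeq) sequenced as paired-end reads of 101 bp. Reads were checked with FastQC 0.11.7 and trimmed with Trimmomatic 0.38. The submitters' processing notes name mm10, edgeR and R 3.6.0. The aligner and the read counter are not given in the sources used here. The deposited table held 15609 genes by NCBI Gene ID, and 15570 of these IDs matched a row of the mouse RefSeq annotation, from which coordinates were taken. Biotypes were those given in the deposited table. The deposited raw counts per gene were the values used for every comparison. The same table gave FPKM and TPM values computed by the authors, which were not used. It also gave deposited log2 values, which equalled log2 of scaled CPM plus 1 in the libraries checked. The 12 FPKM, TPM and log2 columns of the replicated groups were left unused. Comparisons computed by the authors were deposited as signed fold changes, a score that is never between -1 and 1, with mean log2 CPM, and with raw and adjusted p-values, and they are quoted only where named as theirs. The smallest count in the table was 1, so genes with 0 counts in any library had been left out before deposition, and genes switched fully on or off in a group could not be seen. Library totals ran from 49993407 to 63815914 counts, and 1 count equalled 0.0157 to 0.0200 CPM (counts scaled to a common library total).

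Genes were filtered with filterByExpr by group, which kept 15112 genes, and scaled with TMM factors. All 8 libraries entered 1 edgeR (version 4.0.16, R 4.3.3) quasi-likelihood fit with 1 coefficient per group and no other term. The spread came from the 2 replicated groups, which left 2 residual degrees of freedom and a quasi-likelihood prior of 4.14 degrees of freedom, with a common biological coefficient of variation of 0.151. Each lone library was assumed to vary like the replicated groups. Contrasts compared Ly6C+ Sca-1+ with Ly6C+ Sca-1- VM, the mean of the 2 Ly6C+ with the mean of the 2 Ly6C- groups, the Sca-1 difference in Ly6C- with that in Ly6C+ VM, and the mean of the 4 VM groups with naive and with true memory. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are edgeR estimates, and their standard error (SE) was taken from the fold change and the F statistic. Libraries compared as 1 against 1 (true memory with naive, Ly6C- Sca-1+ with Ly6C- Sca-1- VM) were given log2 differences of CPM with a prior count of 2 and no p-value.

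Lists of genes and of cell type markers were tested with camera in limma 3.58.1 (preset correlation 0.01, Benjamini-Hochberg adjusted over 28 lists per comparison), with camera at an estimated correlation and fry beside it. At an estimated correlation camera rests on the 2 residual degrees of freedom, so few lists could keep a call whatever their correlation. For cholesterol biosynthesis in Ly6C+ against Ly6C- VM the estimate was -0.0115, below the preset, yet the camera p rose from 3.3e-07 to 0.031. A call lost there does not show that correlation between genes had made it. The preset lay below most estimates, such as 0.297 for cell cycle genes, so preset p-values can be too small. Gene lists covered interferon-stimulated genes, guanylate-binding proteins with immunity-related GTPases and antigen processing, IL-4 and type 2 associated genes, STAT5 and common gamma chain response, memory-associated, naive-associated, cytotoxic, NK receptor, and trafficking genes. Others covered inhibitory receptor, TCR-response, cell cycle, glycolysis, fatty acid oxidation, cholesterol biosynthesis, heat shock, ribosomal protein and oxidative phosphorylation genes. Markers covered T, B, plasma, monocyte or macrophage, dendritic, NK, CD4 T, gamma delta or innate-like T, erythroid and stromal cells. A platelet list had 1 member in the table and a sex-linked list had 0, so neither was tested. In 1 against 1 comparisons a list's median was placed among 10000 random lists matched on expression. Genes of the random lists were drawn independently, so this rank ignores correlation between genes and spread between libraries. Named genes were the sorting-gate genes, the 10 largest changes in each direction among called protein-coding genes with at least 5 CPM on the higher side, and up to 4 members of each list by smallest p (by largest change where there was no p). With no called gene, the 5 smallest p in each direction were taken as values. Groups, contrasts, lists, this rule and most alternative settings were chosen before the data were examined.

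Alternatives were DESeq2 1.42.0 and limma-voom in place of edgeR, DESeq2 size factors, no filter or a filter of 1 CPM, a minimum fold change, leaving out single libraries, each VM group alone, and prior counts of 0.5 and 10. The fits were tested on simulated counts with known changes in genes with a mean of at least 5 CPM. Simulated genes varied independently and held no difference shared by the A libraries, unlike the real data. The shares recovered below need not hold in the real data. In the Sca-1 comparison within Ly6C+ VM, edgeR recovered 90 of 100 genes changed by 1 log2 and 100 of 100 changed by 2 log2. Beside these 90 and 100 true calls it made 30 false calls, of 15059 genes tested. For Ly6C+ against Ly6C- VM it recovered 93 and 100 of 100, with 18 false calls. For VM against naive it recovered 77 and 100 with 28 false calls, and for VM against true memory 81 and 100 with 21. In the test of the Sca-1 difference between Ly6C- and Ly6C+ it recovered 37 and 92 of 100, with 15 false calls.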

Results

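Transcript counts were obtained from 8 libraries of sorted mouse spleen CD8 T cells: naive (1 library), true memory (1), and VM cells that were Ly6C+ Sca-1- (2), Ly6C+ Sca-1+ (2), Ly6C- Sca-1- (1) and Ly6C- Sca-1+ (1). Total counts were 55750230 for naive, 60460333 and 49993407 for Ly6C+ Sca-1- A and B, and 60898155 and 58854507 for Ly6C+ Sca-1+ A and B. They were 63815914 for Ly6C- Sca-1-, 50911983 for Ly6C- Sca-1+ and 63126280 for true memory. The series compares naive, true memory and the 4 VM subsets in relation to how VM cells develop under cytokines. The first principal component of log2 CPM held 47.1% of the variance and ran from Ly6C+ Sca-1- B at -49.7 to true memory at 69.0. The other 3 Ly6C+ VM libraries lay at -39.7 to -14.1 with naive cells among them at -28.3, and both Ly6C- VM libraries lay at 35.0 and 50.8. The second held 19.7% and set naive cells at 66.5 apart from the other 7 libraries.

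**Figure D1:**
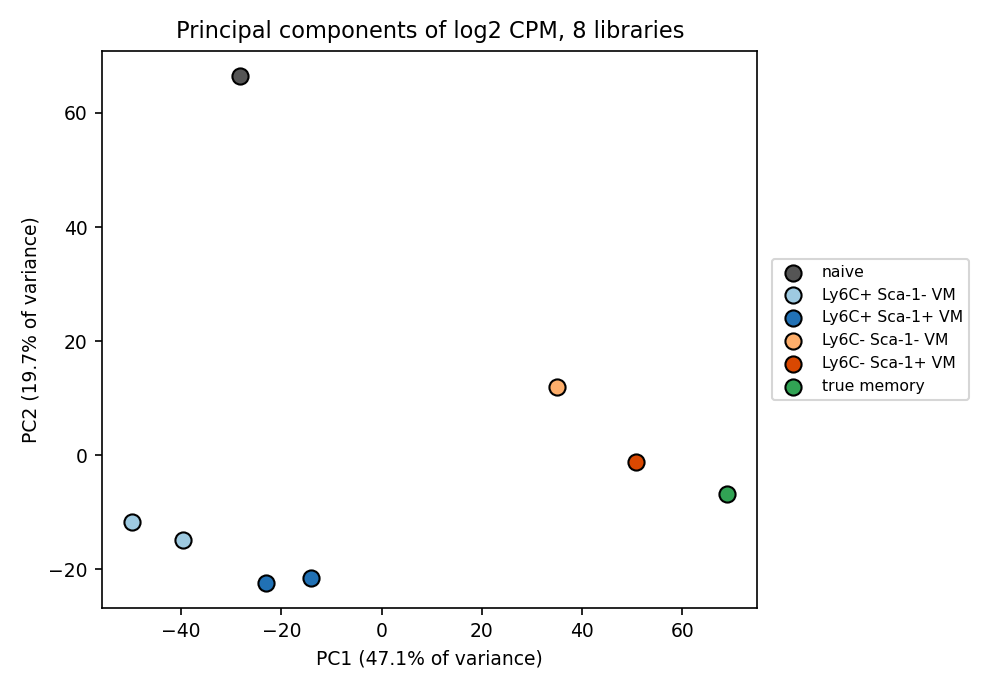
First and second principal components (47.1% and 19.7% of the variance) of log2 CPM, 1 point per library, coloured by group. Naive cells stand apart on the second component at 66.5, and the Ly6C- VM libraries lie between the Ly6C+ VM libraries and true memory on the first.

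Ly6a, Ly6c2 and Cd44 followed the gates of the sort, and Itga4 did so in part. Ly6a (Gene ID 110454, chromosome 15, 74994877 to 74998031 in mm10), which encodes Sca-1, was at 1.91 and 2.54 CPM in Ly6C+ Sca-1- and at 29.4 and 39.8 CPM in Ly6C+ Sca-1+ VM. It was at 3.45 and 62.3 CPM in Ly6C- Sca-1- and Ly6C- Sca-1+ VM. Ly6c2 (Gene ID 100041546, chromosome 15, 75108161 to 75112066), which encodes Ly6C, was at 901 to 1009 CPM in the 4 Ly6C+ libraries and at 54.1 and 75.5 CPM in the Ly6C- libraries. Its near-identical neighbour Ly6c1 (Gene ID 17067) had the same pattern at 74.7 to 83.2 against 4.21 and 6.57 CPM, and how reads were divided between these copies is uncertain. Cd44 was at 6.18 CPM in naive cells and at 130 CPM or more in every other library. Itga4, which encodes CD49d, was at 1367 CPM in true memory, 814 CPM in naive cells and 244 to 564 CPM in VM libraries, although naive and VM cells were both sorted as CD49d-. Cd8a, for the CD8 alpha chain, lay between 1034 and 1317 CPM in all 8 libraries.

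**Figure D2:**
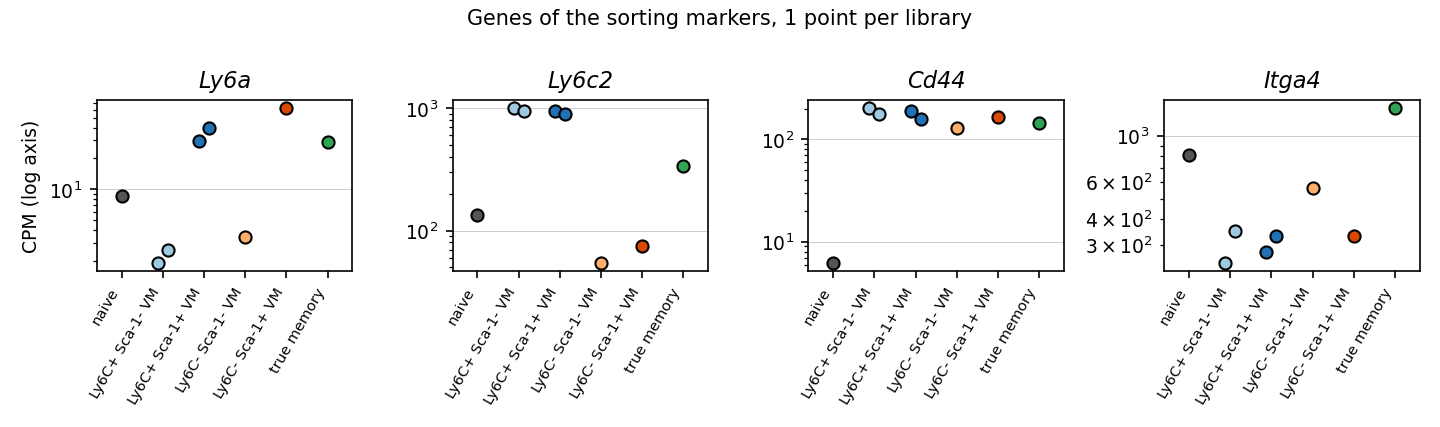
CPM (log axis) of Ly6a, Ly6c2, Cd44 and Itga4 in each library, 1 point per library, grouped by sorted subset. Ly6a lies at 29.4 to 62.3 CPM in the Sca-1+ libraries and at 1.91 to 3.45 CPM in the Sca-1- VM libraries.

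Within Ly6C+ VM cells, the question was how Sca-1+ cells (2 libraries) differ from Sca-1- cells (2 libraries). Ly6a was higher by a log2 fold change of 3.97 ± 0.23 (SE), 3.92 between the A libraries and 3.95 between the B libraries. Cell cycle genes lay higher in Sca-1+ cells as a group: all 38 had a positive log2 fold change, with a median of 0.92, and 30 passed when adjusted over the list alone, against 0 over all genes. Examples were Uhrf1, which maintains DNA methylation at replication (0.87 ± 0.09), the mitotic kinases Bub1 (1.35 ± 0.19) and Aurkb (1.35 ± 0.19), and the mitotic kinesin Kif20a (1.35 ± 0.20). By camera the cell cycle list had an adjusted p = 5.4e-48 at the preset correlation of 0.01, and adjusted p = 0.33 at its estimated correlation of 0.297. Fry gave it an adjusted p = 0.21. Markers of other cells lay higher with it: monocyte and macrophage genes had a median of 2.96 (9 of 9 passing over the list alone), with Csf1r at 36.7 and 51.8 CPM against 6.17 and 1.23. Erythroid genes had a median of 1.84 (4 of 5), with Hbb-bt at 3.27 and 2.31 CPM against 0.537 and 0.396. Camera gave these an adjusted p = 4.5e-21 and 5.6e-11, and adjusted p = 0.33 with an estimated correlation (0.877 and 0.307). By fry they had an adjusted p = 0.30 and 0.21. Dendritic cell and MHC class II genes were positive in 9 of 9 (median 0.79, 0 passing over the list alone), CD4 T cell genes in 4 of 5 (median 0.68, 1 passing) and plasma cell genes in 3 of 3 (median 0.24, 1 passing), with the immunoglobulin joining chain gene Jchain at 3.36 ± 0.42. For these camera gave an adjusted p = 6.9e-07, 0.0029 and 0.014, and adjusted p = 0.43, 0.43 and 0.42 with an estimated correlation.

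Of 41 interferon-stimulated genes 40 had positive values, with a median of 0.14 and 0 past the threshold when adjusted over the list alone or over all genes. Bst2, which tethers virus at the cell surface, was at 0.34 ± 0.09. All 25 genes of guanylate-binding proteins, immunity-related GTPases and antigen processing were positive (median 0.14), and the GTPase Iigp1 (1.52 ± 0.15) passed over the list alone. These lists had camera adjusted p = 1.2e-11 and 4.0e-08, and adjusted p = 0.43 and 0.33 with an estimated correlation. Of the memory list, S100a4 (1.75 ± 0.21), Lgals3, which encodes galectin-3 (2.16 ± 0.26), and Zeb2, a regulator of effector differentiation (1.69 ± 0.23), passed over the list alone, while the median of the 29 members was 0.04. So did Gzmb, for granzyme B (1.58 ± 0.25), the transcription factor Maf (1.79 ± 0.31) and the ectonucleotidase Entpd1 (1.32 ± 0.19). From the naive-associated list the same held for Itgae, for CD103 (1.49 ± 0.28), and Igfbp4 (0.71 ± 0.10). Myeloid cells also make Lgals3 and Zeb2, and monocyte and macrophage markers had a median of 2.96 in this comparison. Whether T cells or such cells supplied the Lgals3 and Zeb2 RNA cannot be told apart in bulk. Lower values that passed over the list alone included those of the NK receptors Klra6 (-1.53 ± 0.29) and Cd160 (-0.47 ± 0.09) and of Ikzf2, for the transcription factor Helios (-1.25 ± 0.26). The 10 NK receptor genes had a median of -0.37 (camera adjusted p = 2.0e-04, and adjusted p = 0.33 with an estimated correlation). Cholesterol biosynthesis genes had a median of 0.12 with 0 of 20 past the threshold over the list alone (camera adjusted p = 0.0013, and adjusted p = 0.33 with an estimated correlation).

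By edgeR, Ly6a was the only one of 15112 genes past the threshold between Ly6C+ Sca-1+ and Sca-1- VM (adjusted p = 0.027), and 650 genes were under an unadjusted p of 0.05, 541 higher and 109 lower. The authors' deposited table for the same 4 libraries called 252 genes, 238 higher and 14 lower, and all 252 had the same direction here. The count depended on the test: limma-voom, no filter and a 1 CPM filter each gave 0 genes, and DESeq2 gave 230. A block by column suffix, added after the data were seen because the A libraries differ from the B libraries in both groups, gave 486. Without library A or B of Ly6C+ Sca-1-, or A of Ly6C+ Sca-1+, edgeR gave 307, 267 and 37 genes, with the lone library assumed to vary like the other groups.

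Ly6C- VM cells offered a separate pair, Sca-1+ and Sca-1- (1 library each, no p-value). Cell cycle genes were higher in Sca-1+ there too: 38 of 38 positive, with a median log2 difference of 0.83 that lay above all 10000 matched random lists. That rank does not measure spread between libraries, and smaller medians reached it too, such as 0.17 for ribosomal protein genes. Plk1, a mitotic kinase, was at 1.26 and the cyclin Ccnb1 at 1.04. Interferon-stimulated genes were positive in 41 of 41 (median 0.33), with the antiviral gene Ifit3 at 0.94 and Mx1 at 0.93. Memory-associated genes were positive in 25 of 29 (median 0.70), among them S100a4 (2.78), S100a6 (2.66), the IL-18 receptor gene Il18r1 (1.90) and the annexin Anxa1 (2.28). So were 18 of 19 cytotoxic and cytokine genes (median 0.26), with Ifng for interferon gamma at 1.68 and Tnf at 1.64. Lower in Sca-1+ were Sox4 (-2.50) and Ccr9, a gut-homing receptor (-1.13), with 18 of 25 naive-associated genes negative (median -0.22), and Ikzf2 (-1.61). CD4 T cell markers moved with them, with Zbtb7b, the regulator of the CD4 lineage, at 2.30 and Cd40lg, for CD40 ligand, at 2.09, as did globin genes (Hbb-bs 1.51) and the plasma cell gene Jchain (3.20). Monocyte and macrophage genes were positive in 8 of 9 (median 0.63), and gamma delta or innate-like T cell genes in 5 of 5 (median 0.59), while dendritic cell and MHC class II genes were positive in 1 of 9 (median -0.50). In all, 112 genes were at least 2-fold higher and 93 at least 2-fold lower of 10174 with 5 CPM or more. Lars2 was lower by -2.30, a value that is uncertain because near-identical copies exist.

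Of the 650 genes under an unadjusted p of 0.05 in Ly6C+ VM, 509 (78.3%) had the same direction in this separate Ly6C- pair, against 57.2% of all 15112 genes. The share was 81.0% for the 541 higher genes and 65.1% for the 109 lower genes. Across genes, which are not independent replicates, the Sca-1 log2 differences of the Ly6C+ and Ly6C- cells had Pearson r = 0.211 and Spearman rho = 0.210. The test of the difference itself, by edgeR, called 0 genes, with 768 under an unadjusted p of 0.05, and 0 by limma-voom and 39 by DESeq2. The block by column suffix, with the lone Ly6C- libraries coded with A, gave 364. Without library A or B of Ly6C+ Sca-1- it called 169 and 109. Of the named genes with the smallest p, 5 had a more positive Sca-1 difference in Ly6C- cells: Itgb1, the integrin beta 1 chain (1.77 ± 0.16, 201 and 744 CPM in Ly6C- Sca-1- and Sca-1+ cells), and the chemokine receptor Cxcr3 (1.35 ± 0.14). The others were Il18rap, for an IL-18 receptor chain (1.23 ± 0.16), the calcium pump Atp2b4 (1.26 ± 0.16) and Tmem154 (1.51 ± 0.20). In the other direction were Gm38495 (-2.36 ± 0.21), which had the smallest p of all, Marcks, a substrate of protein kinase C (-3.99 ± 0.40), Mcmdc2 (-4.33 ± 0.46), the integrin Itgad (-1.89 ± 0.26) and Igfbp4 (-1.18 ± 0.17). Memory-associated genes had a median difference of 0.62, with 15 higher and 2 lower when adjusted over the list alone and 0 over all genes (camera adjusted p = 7.3e-14, and adjusted p = 0.63 with an estimated correlation). For the cell cycle list the median difference was -0.07 (camera adjusted p = 0.99).

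Cell cycle genes and most inhibitory receptor genes were lower in the Ly6C+ than in the Ly6C- VM libraries. All 38 cell cycle genes were lower in Ly6C+ VM (median -2.40), among them Uhrf1 (-2.13 ± 0.08), the ubiquitin-conjugating enzyme Ube2c (-3.17 ± 0.14), the cyclin Ccnb2 (-3.02 ± 0.14) and the checkpoint kinase Bub1b (-2.51 ± 0.12). Of 15 inhibitory receptor and exhaustion-associated genes 10 were lower and 2 higher (median -2.20). Pdcd1, for PD-1 (-3.93 ± 0.29), Lag3 (-3.80 ± 0.34) and Cd200 (-3.15 ± 0.17) were among the lower. Adjusted over the list alone these counts were 38, and 11 lower with 2 higher. Memory-associated genes divided, 9 higher and 14 lower (9 and 15 over the list alone). Il18rap (2.23 ± 0.09) and Cxcr3 (0.89 ± 0.07) were higher, the latter through 45.1 CPM in Ly6C- Sca-1- against 121 in Ly6C- Sca-1+ and 133 to 143 in Ly6C+ libraries. S100a4 (-3.98 ± 0.16) and Lgals3 (-3.74 ± 0.19) were lower. Cytotoxic genes divided as well, 6 higher and 2 lower (6 and 3 over the list alone): Gzmm, for granzyme M (3.08 ± 0.27), and Prf1, for perforin (1.02 ± 0.07), were higher and Gzmb (-2.38 ± 0.20) was lower. The survival gene Bcl2 was higher (1.62 ± 0.12), and the IL-2 receptor alpha gene Il2ra was lower (-3.22 ± 0.25). Of the naive-associated list, 7 genes were higher, such as the IL-7 receptor gene Il7r (1.28 ± 0.13), and 6 lower, such as Itgae (-3.68 ± 0.22) and Sox4 (-2.48 ± 0.21), the same counts as over the list alone.

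Genes of cholesterol and energy metabolism were lower in Ly6C+ VM where they passed, with few exceptions. The ribosomal protein genes that passed over all genes, a minority of the list, were higher. Of 20 cholesterol biosynthesis genes 13 were lower in Ly6C+ VM (16 over the list alone, median -0.53), including the squalene epoxidase gene Sqle (-1.97 ± 0.14). Of 75 nuclear oxidative phosphorylation genes 31 were lower (35 over the list alone, median -0.31). Of glycolysis genes, 7 of 16 were lower and 1 higher (9 and 1 over the list alone), with Hk2, a hexokinase, at -0.97 ± 0.14. Of 81 cytosolic ribosomal protein genes 26 were higher (37 higher and 1 lower over the list alone, median 0.30), such as Rps27 (0.66 ± 0.08). IL-4 and type 2 associated genes were lower in 5 of 8 and higher in 1, also over the list alone, led by the chemokine receptor Ccr4 (-5.99 ± 0.38) and Maf (-2.93 ± 0.24). Fatty acid oxidation genes were lower in 5 of 18 (6 over the list alone, median -0.17). The largest higher folds past the threshold, beside Ly6c1 and Ly6c2 (both 3.90 ± 0.10), were those of the secreted glycoprotein gene Stc2 (4.85 ± 0.30), the Src-family kinase Yes1 (4.06 ± 0.32), the potassium channel Kcnj8 (3.87 ± 0.33) and the scavenger receptor Cd163l1 (3.63 ± 0.13). Large lower folds were those of Lrrc32, which anchors latent TGF-beta (-6.05 ± 0.43), Ccr4, Prr5l (-4.70 ± 0.24), the co-receptor Nrp1 (-4.16 ± 0.17) and the repressor Zbtb32 (-4.16 ± 0.25). Markers of other cells were lower in Ly6C+ VM too: 5 of 5 CD4 T cell genes (median -1.23, 5 over the list alone) and 7 of 9 dendritic cell and MHC class II genes (median -2.28, 8 over the list alone). So were 4 of 5 erythroid genes (median -1.21, 4 over the list alone) and 3 of 3 plasma cell genes (median -2.16, 3 over the list alone). Cd4 was at 3.56 CPM or more in both Ly6C- libraries and at 0.159 to 0.954 CPM in the Ly6C+ libraries. Whether RNA of such cells in the Ly6C- libraries accounts for part of the lower genes, inhibitory receptor genes included, was not tested.

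By edgeR 3240 genes differed between Ly6C+ and Ly6C- VM (4 libraries against 2), 1342 higher and 1898 lower in Ly6C+, and 2876 of them were among the 3244 called in the authors' deposited table. The camera adjusted p was 3.6e-29 for cell cycle, 7.8e-05 for inhibitory, 2.3e-06 for cholesterol and 5.2e-11 for oxidative phosphorylation genes. By camera it was 4.2e-11 for ribosomal, 0.0065 for glycolysis, 0.033 for IL-4, 0.011 for fatty acid oxidation, 3.6e-04 for CD4 T cell, 3.7e-04 for dendritic cell, 0.024 for erythroid and 0.011 for plasma cell genes. With an estimated correlation these had an adjusted p = 0.50 to 0.58. Fry gave an adjusted p = 0.020 for cell cycle, cholesterol and plasma cell genes and 0.041 for inhibitory and CD4 T cell genes. By fry it was 0.049 for oxidative phosphorylation, IL-4 and fatty acid oxidation genes. Ribosomal, glycolysis and dendritic cell genes were at 0.13 by fry, and erythroid genes at 0.10. Each Ly6C- group rests on 1 library: 1370 genes were called without Ly6C- Sca-1- (Sca-1+ groups only), 1126 without Ly6C- Sca-1+ (Sca-1- groups only) and 2039 without library A of Ly6C+ Sca-1+. A minimum 2-fold change left 1221. Other settings raised the count: the block by column suffix, with the Ly6C- libraries coded with A, gave 6601. Leaving out either Ly6C+ Sca-1- library raised it as well.

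**Figure D3:**
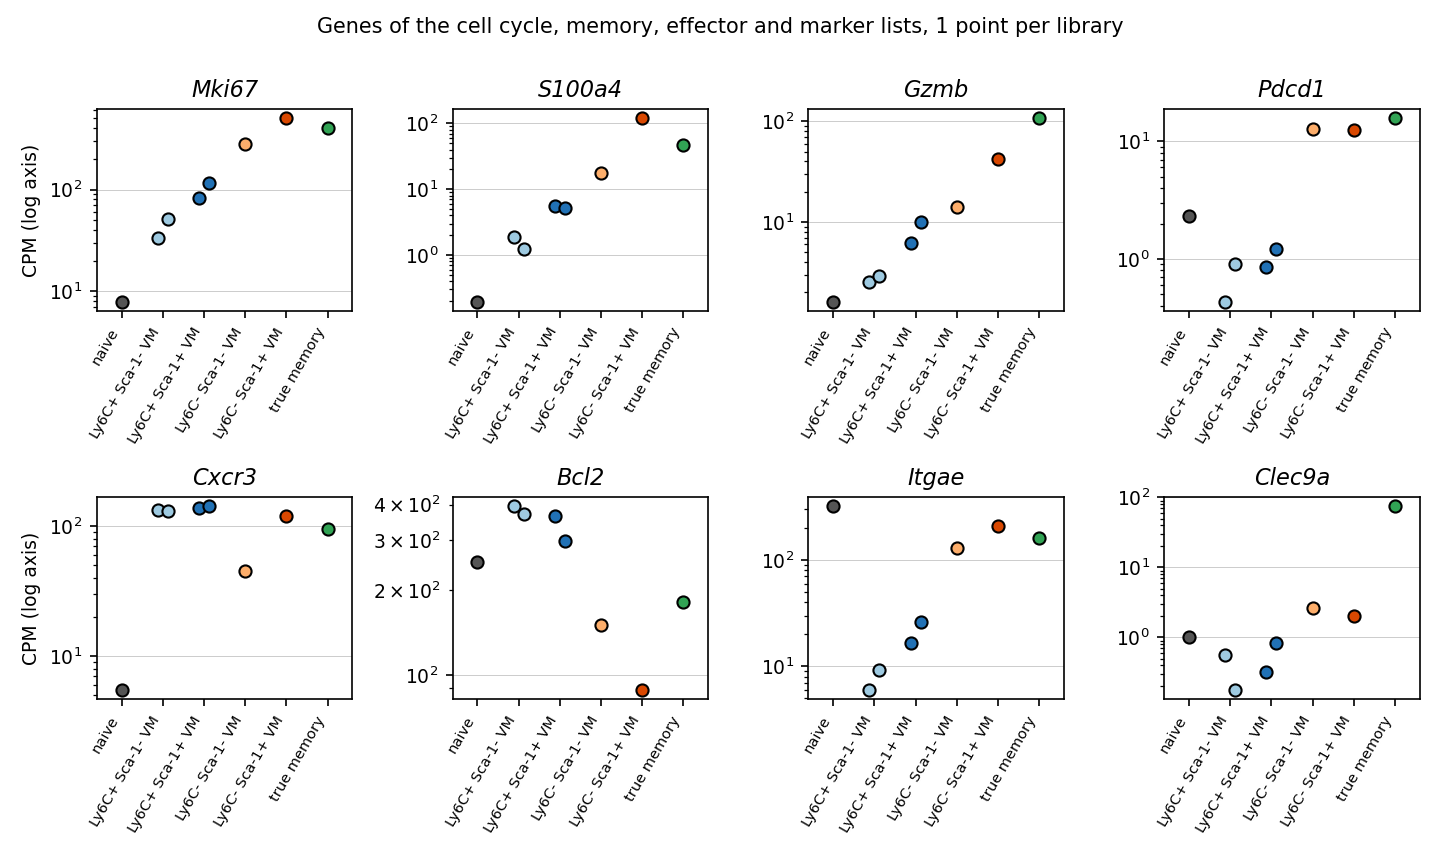
CPM (log axis) of 8 genes in each library, 1 point per library, grouped by sorted subset. Pdcd1 lies higher in both Ly6C- VM libraries (12.7 and 12.6 CPM) than in the 4 Ly6C+ VM libraries, and Clec9a is at 74.4 CPM in true memory.

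VM cells (4 groups, 6 libraries) had higher levels of most memory-associated genes than naive cells (1 library). Of 29 memory-associated genes 20 were higher and 1 lower (26 and 1 over the list alone, median 1.71), including Cxcr3 (4.19 ± 0.12), Il18rap (3.90 ± 0.14), Itgb1 (2.33 ± 0.12) and the transcription factor Eomes (2.38 ± 0.14). Cytotoxic and chemokine genes were higher in 12 of 19 (18 over the list alone, median 1.52), with the chemokine Ccl5 at 5.02 ± 0.35 and Fasl, which encodes Fas ligand, at 5.34 ± 0.55. NK receptor genes were higher in 6 of 10 and lower in 1 (7 and 1 over the list alone, median 1.73), led by Klrc1, for NKG2A (7.16 ± 0.32), and Klra3 (4.26 ± 0.44). Trafficking receptors were higher in 6 of 14 and lower in 1 (9 and 3 over the list alone, median 1.35), among them Cxcr5 (3.51 ± 0.16). Cell cycle genes were higher in 36 of 38 (38 over the list alone, median 2.78), with Ube2c at 4.73 ± 0.29 and Bub1 at 4.45 ± 0.30. Inhibitory genes were higher in 5 of 15 (8 over the list alone, median 0.81), such as Tigit (3.18 ± 0.35), and glycolysis genes in 5 of 16 (9 over the list alone, median 0.44), such as Hk2 (2.04 ± 0.21). The Ly6C- libraries carried most of the inhibitory list's rise, at a mean log2 CPM of 4.922 (Sca-1-) and 4.717 (Sca-1+). The 4 Ly6C+ VM libraries were at 2.625 to 3.197, near naive cells at 2.682.

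Naive-associated genes were lower in VM in 4 of 25 (6 over the list alone, median -0.28): Igfbp4 (-2.92 ± 0.09), Itgae (-2.79 ± 0.24), Ccr9 (-3.50 ± 0.40) and Lef1, a transcription factor of naive and stem-like T cells (-0.81 ± 0.12). Among the largest changes past the threshold were also S100a4 (5.86 ± 0.36), Samd3 (5.75 ± 0.16), Plek, for pleckstrin (5.30 ± 0.17), and, in the other direction, the receptor genes Gpr83 (-3.46 ± 0.27) and Ntrk3 (-2.25 ± 0.17). S100a4 was at 17.3 and 120 CPM in Ly6C- Sca-1- and Sca-1+ VM, 1.23 to 5.46 CPM in Ly6C+ VM and 0.195 CPM in naive cells. IL-4 and type 2 associated genes were higher in 2 of 8 (3 over the list alone, median 0.60), namely Nfil3 (2.69 ± 0.25) and Maf (3.10 ± 0.41). Maf was at 9.33 and 12.9 CPM in the Ly6C- libraries, 0.634 to 3.16 CPM in Ly6C+ VM and 0.462 CPM in naive cells. STAT5 response genes were higher in 2 of 17 (2 over the list alone, median -0.03), such as the survival gene Bcl2l1 (1.33 ± 0.21). Ly6c2 was higher in VM as a mean (0.87 ± 0.11) but at -1.32 in Ly6C- Sca-1- and -0.84 in Ly6C- Sca-1+ cells alone. Among markers of other cells, 1 of 9 monocyte and macrophage genes was higher (1 over the list alone, median 2.23), C1qb (2.96 ± 0.56), and 2 of 5 NK cell genes (5 over the list alone, median 1.72), 1 of which, Eomes, also stands in the memory list. CD4 T cell genes were higher in 2 of 5 (4 over the list alone, median 1.62), with Zbtb7b at 4.24 ± 0.49, and 0 of 5 erythroid genes passed (4 over the list alone, median 1.54). Camera gave these an adjusted p = 0.0017 and 0.0057, and adjusted p = 0.36 with an estimated correlation.

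In this comparison edgeR called 815 genes, 592 higher and 223 lower in VM. A 2-fold minimum left 534, and the block by column suffix, with the naive library coded with A, gave 4019. The camera adjusted p was 1.5e-24 for memory, 1.6e-15 for cytotoxic, 2.5e-06 for NK receptor, 4.3e-05 for trafficking and 5.3e-41 for cell cycle genes. By camera it was also 2.4e-05 for inhibitory, 5.8e-06 for glycolysis, 2.0e-06 for naive-associated, 0.0012 for IL-4, 9.7e-04 for monocyte and 1.6e-05 for NK cell genes. With an estimated correlation these had an adjusted p = 0.26 to 0.52. Fry gave an adjusted p under 0.05 to the memory, cytotoxic, NK receptor, trafficking, cell cycle, naive-associated and NK cell lists. It did not for the inhibitory, glycolysis, IL-4 and monocyte lists. The naive group was 1 library, DESeq2 called 1346 genes, and edgeR called 1902 and 1918 without library A or B of Ly6C+ Sca-1-.

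The true memory library differed from VM mostly through genes that were lower in VM. RNA of other cells in that 1 library was not separated from RNA of true memory T cells. All 9 dendritic cell and MHC class II genes were lower in VM (9 over the list alone, median -5.49). Among them were Clec9a (-6.16 ± 0.37) and Xcr1 (-6.06 ± 0.45), markers of cross-presenting dendritic cells, the cytokine receptor Flt3 (-5.87 ± 0.21), the transcription factor Zbtb46 (-5.42 ± 0.21) and the class II gene H2-Eb1 (-5.49 ± 0.36). Cd74, the invariant chain of MHC class II, was at 2062 CPM in true memory and at 9.08 to 151 CPM in the VM libraries. Of the cytotoxic list, 5 of 19 genes were lower in VM (7 lower and 2 higher over the list alone, median -0.29), including Gzma, for granzyme A (-4.56 ± 0.44), and Gzmb (-3.33 ± 0.21). So were 5 of 15 inhibitory genes (6 lower and 1 higher over the list alone, median -0.45), including Havcr2, for TIM-3 (-5.10 ± 0.32), Cd244a (-4.65 ± 0.35) and Entpd1 (-2.12 ± 0.17), and Havcr2 is also made by dendritic cells. Of 29 memory-associated genes 11 were lower and 1 higher (14 and 1 over the list alone, median -0.33), with Lgals3 at -3.62 ± 0.19 and Zeb2 at -3.19 ± 0.19, which myeloid cells also make. The trafficking receptors Cx3cr1 (-4.50 ± 0.40) and Itgax (-2.98 ± 0.12), both also made by myeloid cells, were 2 of 4 lower trafficking genes, with 2 higher (5 and 2 over the list alone).

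Cell cycle genes were lower in VM in 22 of 38 (34 over the list alone, median -1.20), such as Ube2c (-1.71 ± 0.16), which was at 0.37 for Ly6C- Sca-1+ VM alone. The whole list lay higher in that VM library than in true memory, at a mean log2 CPM of 6.26 against 5.83, and lower in the other 5. S100a4 (-2.03 ± 0.17) likewise was at 1.35 for Ly6C- Sca-1+ VM alone, and Ly6a (-1.34 ± 0.19) at 1.12 for Ly6C- Sca-1+ and 0.27 for Ly6C+ Sca-1+ VM alone. Genes higher in VM were few and included the scavenger receptor family gene 5830411N06Rik (2.07 ± 0.14), Cxcr5 (0.91 ± 0.12), the oxysterol receptor Gpr183 (0.79 ± 0.14), the transcription factor Myb (0.74 ± 0.14) and Eomes (0.70 ± 0.12). Xntrpc was also higher (1.53 ± 0.21), an uncertain value because its reads are shared with an overlapping near-identical gene. Markers of other cells were lower in VM for 2 of 9 monocyte and macrophage genes (3 over the list alone, median -1.04), with Mpeg1 at 538 CPM in true memory. So were 2 of 5 NK cell genes, with Eomes higher (4 and 1 over the list alone, median -1.98), and 1 of 3 plasma cell genes (2 over the list alone, median -1.30). Of 5 gamma delta or innate-like T cell genes 1 was lower (3 over the list alone, median -0.91), and of 5 erythroid genes 0 (3 over the list alone, all 5 negative). Camera gave these an adjusted p = 0.0056 and 0.016, and adjusted p = 0.40 with an estimated correlation.

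By edgeR 691 genes differed between VM and true memory, 21 higher and 670 lower in VM. How many of the 670 come from RNA of other cells in the true memory library was not tested. The block by column suffix, with the true memory library coded with A, gave 2604. Camera gave an adjusted p = 5.3e-16 for dendritic cell, 0.016 for cytotoxic, 0.0012 for inhibitory, 1.3e-06 for memory, 1.0e-23 for cell cycle, 0.016 for monocyte, 0.018 for NK cell and 0.025 for plasma cell genes, and adjusted p = 0.40 to 0.65 with an estimated correlation. True memory was 1 library, and taken alone the VM groups differed from it in 1405 (Ly6C+ Sca-1-), 1134 (Ly6C+ Sca-1+), 205 (Ly6C- Sca-1-) and 164 genes (Ly6C- Sca-1+). Without library A or B of Ly6C+ Sca-1- the count was 1251 and 1236.

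Compared with naive cells (1 library against 1, no p-value), true memory cells had higher memory-associated genes in 28 of 29 (median log2 difference 2.31). S100a4 was at 7.67 and Bhlhe40, a transcription factor of tissue-resident and effector cells, at 6.13. They had higher cytotoxic genes in 18 of 19 (median 2.25), such as Gzma (8.88) and Ccl5 (6.50). Cell cycle genes were higher in 38 of 38 (median 3.82), with the proliferation marker Mki67 at 403 against 7.94 CPM. Inhibitory genes were higher in 14 of 15 (median 2.35), such as Havcr2 (6.07) and Lag3 (4.80). Naive-associated genes were lower in 23 of 25 (median -0.49), with Igfbp4 at -1.55. Dendritic cell and MHC class II genes were higher in 9 of 9 (median 5.59), and monocyte and macrophage genes in 9 of 9 (median 2.50). So were NK cell (median 3.53), erythroid (2.51) and gamma delta or innate-like T cell genes (2.07) in 5 of 5 each, plasma cell genes in 3 of 3 (2.95) and CD4 T cell genes in 4 of 5 (1.45). Cx3cr1 was at 3377 counts in true memory and at 3 counts in naive cells, so its ratio rests on few counts. In all, 880 genes were at least 2-fold higher and 40 at least 2-fold lower of 10419 with 5 CPM or more. RNA of other cells in the true memory library was not separated here either.

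**Figure D4:**
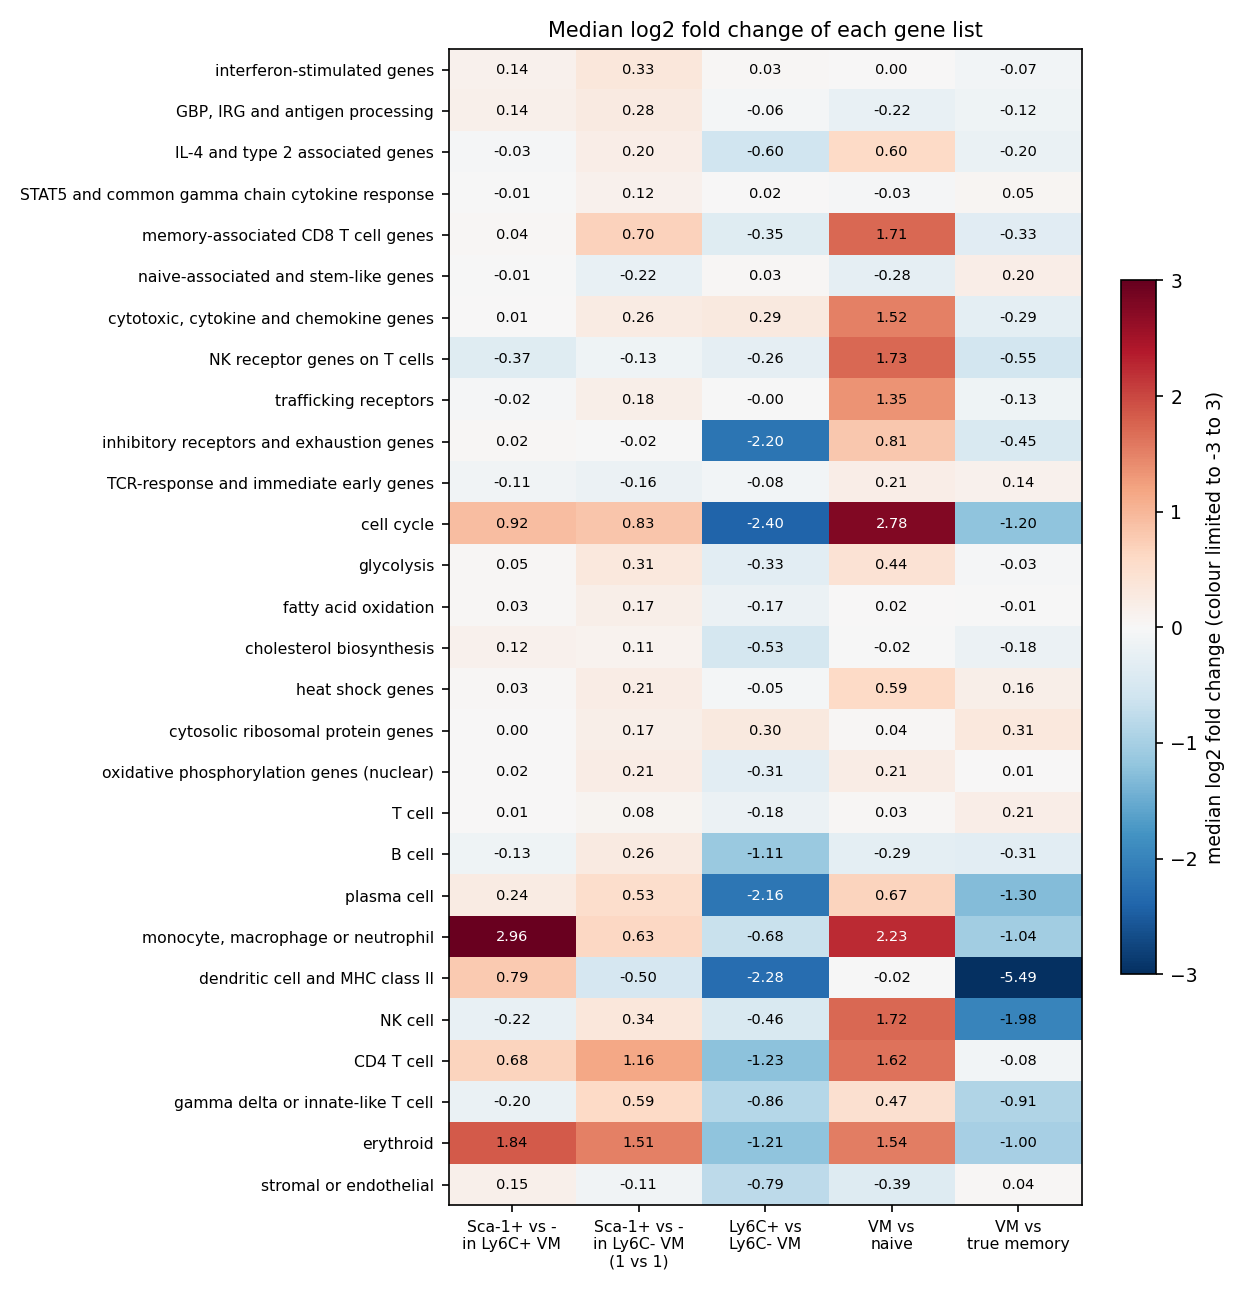
Median log2 fold change of each gene or marker list in 5 comparisons, by colour (limited to -3 to 3) and printed value. Cell cycle genes are at 0.92 and 0.83 for Sca-1+ against Sca-1- cells in Ly6C+ and Ly6C- VM and at -2.40 for Ly6C+ against Ly6C- VM.

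T cell genes had medians of 0.01 for Sca-1 in Ly6C+ VM, -0.18 for Ly6C+ against Ly6C- VM (4 of 11 lower, 4 over the list alone), 0.03 for VM against naive and 0.21 for VM against true memory. Camera called those of Ly6C+ against Ly6C- VM and VM against true memory at an adjusted p = 0.036 and 1.2e-04, and neither with an estimated correlation (adjusted p = 0.58 and 0.40). TCR-response and immediate early genes had 4 of 23 lower in Ly6C+ than Ly6C- VM (4 over the list alone, median -0.08), such as the activation gene Egr2 (-0.89 ± 0.13), and 2 higher with 1 lower in VM against naive (3 and 1 over the list alone, median 0.21). On these genes the Ly6C+ A libraries (mean log2 CPM 8.08 and 7.90) lay above both Ly6C- libraries (7.81 and 7.68). The B libraries, at 7.07 and 7.12, lay below the Ly6C- libraries and below naive cells (7.20). Heat shock genes had a median of 0.59 in VM against naive, with Hspd1 alone past the threshold (1 over the list alone; camera adjusted p = 0.0038, and adjusted p = 0.54 with an estimated correlation). The A libraries were the highest on this list (mean log2 CPM 8.47 in both), while Ly6C+ Sca-1- B, at 7.19, lay below naive cells at 7.46. B cell genes were lower in 4 of 10 and higher in 1 in Ly6C+ against Ly6C- VM (7 and 2 over the list alone, median -1.11). Of 5 gamma delta or innate-like T cell genes 2 were lower there (3 lower and 1 higher over the list alone, median -0.86), and of 3 stromal or endothelial genes 1 (3 over the list alone, median -0.79; camera adjusted p = 0.039, and adjusted p = 0.50 with an estimated correlation). Ribosomal protein genes had a median of 0.31 in VM against true memory, with 0 past the threshold over all genes or the list alone (camera adjusted p = 1.6e-23, and adjusted p = 0.40 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.21 in VM against naive, also with 0 past the threshold over all genes or the list alone (camera adjusted p = 1.1e-06, and adjusted p = 0.36 with an estimated correlation). NK receptor genes were lower in VM than in true memory in 2 of 10 (7 lower and 1 higher over the list alone, median -0.55; camera adjusted p = 0.0094, and adjusted p = 0.40 with an estimated correlation).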

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

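The tests weighed here were chosen after the results were seen, except that of a second dendritic cell list and the planned test of whether the Sca-1 difference differs between Ly6C- and Ly6C+ VM. That planned test called 10 lists by camera, none of which kept its call with an estimated correlation (adjusted p = 0.63 to 0.72). With 2 residual degrees of freedom that second test could hardly keep a call, so it does not decide whether the 10 calls hold. Fry called none of them (adjusted p = 0.62 to 0.76). The median difference, Ly6C- minus Ly6C+, was 0.62 for memory-associated genes (29 members), 0.15 for interferon-stimulated genes (41), 0.26 for cytotoxic genes (19), 0.27 for glycolysis genes (16), 0.17 for ribosomal protein genes (81) and 0.18 for oxidative phosphorylation genes (75). It was -0.20 for naive-associated genes (25), -0.36 for inhibitory genes (15), -2.35 for monocyte and macrophage markers (9) and -1.36 for dendritic cell and MHC class II genes (9). In monocyte and macrophage markers the Sca-1 difference was 2.96 in Ly6C+ and 0.63 in Ly6C- cells.

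Dendritic cell and MHC class II genes were high in the true memory library, with a median of 6.02 (log2) above the other 7 libraries, and of 5.93 for the 4 class II genes, and Cd74 was at 2062 CPM. B cells as the source of the class II genes are argued against by the B cell list, whose median of 0.35 lay 5.58 below that of the class II genes (SD of its members 1.28). RNA of dendritic cells is a candidate explanation that stays open: of a second list of dendritic cell genes, fixed before its values were looked up, 6 of 8 measured members (75.0%) were at least 8-fold above the other libraries, short of the 80% set beforehand, with a median of 4.73. H2-DMa and H2-Oa missed, and both are also present in the T cell libraries, at a median of 22.3 and 21.3 CPM elsewhere, while the T cell list was at -0.16 in true memory with 8 of 11 members lower. Sorting on CD8, CD44 and CD49d would remove cells that lack CD8, yet some spleen dendritic cells carry CD8 alpha, and RNA of such cells cannot be told apart in bulk from expression of these genes by true memory T cells, which was not tested.

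Cell cycle genes were higher in Sca-1+ than in Sca-1- VM libraries in each of 3 pairs that share no library, with 36 of 38 genes positive in all 3. RNA of macrophages or erythroid cells, whose markers were also higher in each pair, stays open, although bead enrichment and the sort on CD8 would remove cells that lack CD8. The CPM gained by the cell cycle genes was 3.17, 2.28 and 38.2 times that gained by the monocyte and macrophage list in the A, B and Ly6C- pairs, and at least 21.8 times that gained by the erythroid list. No table gives the share of cell cycle RNA in such cells, so these ratios exclude neither. A larger share of dividing T cells among Sca-1+ VM cells may account for the pattern, as may dividing cells of another type, and neither was tested.

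Both A libraries differed from both B libraries in immediate early and heat shock genes. The authors' deposited table, which also compares the 2 libraries within a group, called 687 genes in Ly6C+ Sca-1- and 492 in Ly6C+ Sca-1+ VM. Immediate early genes had a median A minus B log2 difference of 1.06 and 0.92 in these groups, with 22 of 23 higher in A in both, and heat shock genes 0.41 and 0.46, while cell cycle genes were at -0.29 in both. The A minus B differences of the groups, which share no library, correlated across 15112 genes with r = 0.354 (rho 0.453, and r = 0.346 without those lists), which is consistent with a difference shared by the A libraries. The labels name no factor that would separate A from B, so no biological explanation was tested.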

How the results depend on the processing

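The replicate block by column suffix and the fits without the true memory library were chosen after the data were seen. With DESeq2 size factors, 815 genes for VM against naive, 1 for Sca-1 in Ly6C+ and 0 for the Sca-1 difference between Ly6C- and Ly6C+ were unmoved, and 3259 and 688 replaced 3240 and 691. Where a count moved by more than 1.5 times, the cause was not tested, except that a 2-fold minimum keeps fewer genes and a lower CPM minimum admits more by construction. Sca-1 in Ly6C+ (1 gene) gave 0 with no filter, with 1 CPM and with limma-voom, and 230 with DESeq2. DESeq2 gave 39 for the Sca-1 difference between Ly6C- and Ly6C+ (0 with edgeR) and 1346 for VM against naive. A 2-fold minimum gave 1221 for Ly6C+ against Ly6C- and 534 for VM against naive. Alone against true memory, the Ly6C+ groups gave 1405 (Sca-1-) and 1134 (Sca-1+), and the Ly6C- groups 205 and 164. A minimum of 1 CPM gave 1413 genes of at least 2-fold for true memory against naive (920) and 457 for the Ly6C- Sca-1 pair (205).

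Leaving out single libraries gave 1 to 307 genes for Sca-1 in Ly6C+ (highest without Ly6C+ Sca-1- A), 1126 to 4381 for Ly6C+ against Ly6C-, 0 to 169 for the Sca-1 difference between Ly6C- and Ly6C+, 673 to 1918 for VM against naive and 680 to 1251 for VM against true memory. The planned replicate block by number could not be run, since the columns carry no numbers. The main fit has no block, so a difference shared by the A libraries entered its estimate of the spread. A replicate block by suffix gave 486 genes for Sca-1 in the 4 Ly6C+ libraries. Only 2 pairs of libraries inform it, and the labels do not state it as a pairing. With all 8 libraries it gave 467, 6601 for Ly6C+ against Ly6C-, 364 for the Sca-1 difference, 4019 for VM against naive and 2604 for VM against true memory. In that fit the lone libraries, whose columns carry no suffix, were coded with A. Its counts for comparisons with a lone library rest on that coding, which was not tested. Of 140 list tests camera called 66, 67 with DESeq2 size factors, 17 by fry and 0 with an estimated correlation. All fry calls were in Ly6C+ against Ly6C- VM or in VM against naive. Camera with an estimated correlation could hardly call a list with 2 residual degrees of freedom. Of the genes named above for each comparison, the only ones checked for this, sign changed only for single VM groups. Against naive, Ly6c2 was -1.32 in Ly6C- Sca-1- and -0.84 in Ly6C- Sca-1+. Other called genes also turn: Ly6c1, higher in VM as a mean, was at 4.21 and 6.57 CPM in the Ly6C- libraries and 10.5 CPM in naive cells. Against true memory, Ly6C- Sca-1+ gave 1.12 for Ly6a, 1.35 for S100a4 and 0.37 for Ube2c, and Ly6C+ Sca-1+ gave 0.27 for Ly6a. Depth limits the genes near 1 count, 0.0157 to 0.0200 CPM.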

Other observations

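Among neighbours of Ly6a on chromosome 15, Ly6e was also higher in Sca-1+ than in Sca-1- VM libraries, by less than Ly6a, and it did not pass the edgeR test within Ly6C+ VM. Ly6e, at 74955025 to 74959904, was at 527 CPM in naive, 758 and 722 CPM in Ly6C+ Sca-1-, 827 and 814 CPM in Ly6C+ Sca-1+, 705 and 969 CPM in Ly6C- Sca-1- and Sca-1+ VM and 769 CPM in true memory. Lynx1 and Ly6k were at 3.78 CPM or less in all 8 libraries, and Ly6d at 1.28 CPM or less outside true memory (6.06 CPM). T cell receptor beta variable segments were counted to compare the repertoires in bulk, a test chosen after the data were seen. The 23 segments in the table drew 21450 to 30749 counts per library, and of 19 segments with a mean share of at least 1% naive cells lay outside the range of the 6 VM libraries in 5, where chance gives 28.6% of segments.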
